A study of Mus musculus with 4 samples.

How the data were processed

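RNA-seq was performed on total RNA from mouse tumours grown from CT26, a BALB/c colon carcinoma cell line. The cells had been made either deficient in IL-34 or to overexpress it, and the tumours were either untreated or treated with an anti-PD-1 antibody. Per the labels, RNA was extracted with a PureLink RNA Mini Kit and libraries were made with a SureSelect strand-specific kit. There were 4 libraries, 1 per group, and the labels do not say how many animals stood behind a library, how long they were treated or when tumours were taken.

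The authors deposited 1 table of FPKM values, fragments per kilobase of transcript scaled to the mapped fragments of the library, for 23745 gene rows. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.1.0 and Cufflinks 2.2.1 were used with the mm10 build. Their order and settings, including the strand setting of the counting, are not given in the sources used here. The RefSeq accessions in the table show that RefSeq gene models were used. Coordinates are those of the table on mm10, given from base 1. The table also had 1 emptied line, which was not used.

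FPKM is scaled to mapped fragments and transcript length, so a library with a few very abundant transcripts has lower values for all others, and the sums of FPKM differed between libraries. Reads that match several near-identical genes, such as the granzyme D to G genes, can be divided among them by Cufflinks, so values of single members are uncertain. The same holds for models that overlap another model, among them BC002163, Oaz1-ps and the Rps27 model, whose values are given as uncertain. Total fragment counts are not recoverable from FPKM. Relative depth was read from values below 0.1 FPKM, where a single fragment sets the size of the step: the most frequent ratio between libraries, within a tolerance of 0.01, gave each library's depth relative to the untreated IL-34-deficient library. Without counts, no counting interval was computed.

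Where a symbol had several rows, the row with the highest mean was used, and 773 symbols of short RNAs were left out, which left 22510 symbols. Ratios were taken as log2 of FPKM + 1, which understates differences of genes with low values, and folds are plain FPKM ratios. As each group has 1 library, the 4 pairwise comparisons and the difference of the anti-PD-1 responses were described without a test. Genes were counted where the log2 ratio was at least 1 in size and FPKM was at least 1 in at least 1 of the libraries compared. For each of 46 gene lists holding 599 genes, of which 1 was not matched by symbol, the median log2 ratio of members with FPKM of at least 1 was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A median below the 2.5th or above the 97.5th percentile is called apart, which describes these libraries and not the conditions. By chance, 5% of lists would lie apart if their members varied independently. Members of a list can vary together between single libraries, so more lists could lie apart without any effect of the conditions.

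The effects of IL-34 over both treatments and of anti-PD-1 over both lines were tested with limma 3.58.1 in R 4.3.3 on log2 of FPKM + 1 with a mean-variance trend, over 11814 genes with FPKM of at least 1 in at least 1 library. The additive fit left 1 residual degree of freedom, which is the interaction of line and treatment, so any real difference in response counts as error. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Other computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

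The limma fit was tested on simulated data for these 11814 genes, with 200 genes changed and Gaussian noise without an interaction of line and treatment. With noise of the size of the spread in the additive fit, it recovered 83.75% of genes changed by a log2 of 1 for the IL-34 effect and 92.5% for the anti-PD-1 effect, and 100% of those changed by 2 or 4. Among 11614 unchanged genes it made 12 and 17 calls. With noise of the spread among the 3 libraries that lay close together, the share at a log2 of 1 was 98.75% for each effect, with 16 and 15 such calls. These shares show that the fit finds what was put in, and do not give its power on the real data, where Saa3, Gzmf, Gzmd and BC002163 had log2 differences of at least 1 in size with IL-34 and were not called. In simulated lists for the anti-PD-1 comparison of IL-34-deficient tumours, 9 of 200 unchanged lists lay apart, as did 50 of 50 lists shifted by a log2 of 0.5. These lists held random genes with independent noise, so they do not give the rate for lists whose members vary together.

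The groups, the comparisons, the gene lists, the tests, the alternatives and the rule for the genes named were chosen before the data were examined. That rule took the genes of the IL-34 and PD-1 axes first. It then took the 8 highest and 8 lowest genes of each comparison with FPKM of at least 5, and the 8 each way that moved in the same direction in both pairs, leaving out predicted models and short RNAs. It added up to 4 members with the largest ratio from each list that lay apart, and let any list member be given where lists are compared. The alternatives were pseudocounts of 0.1 and 5, no FPKM minimum or a minimum of 5, a size of 1.5, short RNAs kept, 10 bins, the mean in place of the median, and other scalings (median ratio, upper quartile, TPM and quantile). For limma they also included no trend, no second factor and leaving out each library in turn. Counts without the genes of the epidermis, skeletal muscle and adipocyte lists were added after the data had been seen. Only the members of these lists were left out, so other genes of these tissues remained in such counts.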

Results

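IL-34 is a cytokine that signals through the CSF-1 receptor, the receptor that also governs the survival of macrophages, and PD-1 is an inhibitory receptor of T cells that antibodies can block. The study asked whether IL-34 made by tumour cells limits the response to PD-1 blockade. Gene expression was measured by RNA-seq in CT26 tumours of 4 groups, IL-34-deficient and IL-34-overexpressing, each untreated and treated with anti-PD-1, with 1 library per group. No group had a replicate, so no spread within a group could be measured and no value below has a replicate check. The limma results take the interaction of line and treatment as error, which is not a spread among replicates. The FPKM sums were 543926 in the untreated IL-34-deficient library, 488881 in the anti-PD-1 IL-34-deficient library, 523753 in the untreated IL-34-overexpressing library and 518464 in the anti-PD-1 IL-34-overexpressing library. Relative to the first, the depths of the other 3 libraries were 92.8%, 95.2% and 90.0%. Between 11355 and 11634 gene rows had FPKM of at least 1. Across genes, the anti-PD-1 IL-34-deficient library correlated with the other libraries at r of 0.975 to 0.982, and the other libraries with each other at r of 0.994 to 0.996; genes are not independent replicates.

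Il34 itself (chromosome 8, 110741829 to 110805903) was at 3.52 and 3.02 FPKM in the untreated and treated IL-34-deficient libraries and at 104 FPKM in both IL-34-overexpressing libraries. It was 29.4-fold higher in the overexpressing line without treatment and 34.4-fold higher with anti-PD-1, the direction of the labels. The part of the gene that was disrupted is not given in the sources used here, so the remaining FPKM in the deficient line does not show whether the transcript was intact. Csf1r, the receptor of IL-34, was at 78.3 FPKM in untreated deficient tumours, 118 in treated deficient tumours, 79.7 in untreated overexpressing tumours and 70.4 in treated overexpressing tumours. Csf1, the other ligand of this receptor, ranged from 71.9 to 96.7 FPKM and Sdc1, a proteoglycan that binds IL-34, from 14.9 to 15.4 FPKM. Ptprz1, another reported receptor, was listed at 0 in every library. The median of this list lay apart in none of the 5 comparisons.

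The first comparison asked how tumours of IL-34-deficient cells responded to anti-PD-1. In the deficient line the treated library had higher levels of genes of T cells, antigen presentation, macrophages and interferon-γ signalling than the untreated library. Cd8a, the coreceptor of cytotoxic T cells (chromosome 6, 71373427 to 71379171), was at 20.2 against 8.61 FPKM, a fold of 2.35, and Cd3e, a chain of the T cell receptor complex, at 28.5 against 12.8 FPKM. Ifng, which encodes interferon-γ, was 2.75-fold higher, at 11.8 against 4.30 FPKM. Cd74, the invariant chain of MHC class II (chromosome 18, 60803849 to 60812652), was 2.66-fold higher, at 3978 against 1498 FPKM.

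The T cell receptor and pan-T cell list had a median log2 ratio of 0.80 over 14 members, of which 3 were higher by a log2 of at least 1 and 0 lower. The CD4 and CD8 lineage list had a median of 1.14, with all 3 members past that size. Inhibitory receptors of T cells had a median of 0.69 over 8 members, and Lag3 among them was at 19.3 against 6.66 FPKM. On the PD-1 axis the median was 1.0, with 2 of 3 members higher by size. Pdcd1, which encodes PD-1, was at 13.1 against 7.56 FPKM, and its ligands Cd274 and Pdcd1lg2 were at 46.8 against 22.8 and 8.18 against 1.84 FPKM. The regulatory T cell list had a median of 0.52 and the naive and memory T cell list one of 0.34, which did not lie apart when the mean (0.38 and 0.24) replaced the median. The natural killer cell list had a median of 0.63 over 8 members.

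MHC class II presentation had a median of 1.15, with 7 of 9 members higher by size, among them H2-Ab1 at 976 against 332 FPKM and H2-Eb1 at 610 against 202 FPKM. MHC class I presentation had a median of 0.50 over 14 members, with 0 past the size. The interferon-γ response list had a median of 0.83 over 24 members and the type I interferon list one of 0.61 over 20. Chemokines that attract T cells had a median of 0.99, with Ccl5 at 223 against 41.5 FPKM, a fold of 5.38, and Cxcl9 at 219 against 110 FPKM. Pan-macrophage genes had a median of 0.79 over 16 members and complement genes one of 0.82 over 13, with C3 at 125 against 44.1 FPKM. Alternatively activated macrophage genes had a median of 0.38, although Mrc1 was at 48.6 against 43.2 FPKM and Arg1 at 122 against 131 FPKM. Classically activated macrophage genes had a median of 0.50, inflammatory monocyte genes one of 0.45 and plasmacytoid dendritic cell genes one of 0.78. The last list holds Ly6d and Cox6a2, which are not specific to these cells, so its median need not reflect them alone. The mast cell, eosinophil and basophil list had a median of 1.43 over 7 members, with the mast cell proteases Tpsb2 at 132 against 35.7 FPKM and Mcpt4 at 56.0 against 17.3 FPKM.

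The cytotoxic effector list was divided. Its median was 0.52 over 16 members, with 5 higher and 4 lower by size, and it did not lie apart with the mean of 0.14. Gzmb, which encodes the protease granzyme B, was at 96.2 against 70.7 FPKM and Prf1, the pore-forming perforin, at 33.3 against 22.0 FPKM. Granzymes C to G, encoded next to each other on chromosome 14 (56117619 to 56234656), were lower with anti-PD-1. Gzmd was at 6.83 against 46.0 FPKM, Gzmg at 7.47 against 53.2 FPKM and Gzmf at 9.15 against 53.8 FPKM. Glycolysis and hypoxia genes also had a lower median, −0.58 over 20 members with 5 lower by size. Car9, a carbonic anhydrase induced by hypoxia, was at 4.89 against 19.0 FPKM. Epithelial genes had the lowest median, −1.56 over 5 members, with 3 lower by size. Those 3 (Krt8, Krt18 and Krt19) passed the FPKM minimum only through the untreated library, so a lower value followed in part from the filter. Ribosomal protein genes had a median of −0.54, neutrophil genes one of −0.43 and endothelial genes one of −0.31.

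Genes of epidermis and skeletal muscle were higher in the same treated library, and their source was not tested. The epidermis and hair follicle list had a median of 2.72, with all 10 members higher by size, and the skeletal muscle list one of 1.71, with 14 of 15 higher. Median FPKM of the epidermis list was 9.99 in this library, 0.339 in the untreated deficient library and 0 and 0.0179 in the overexpressing libraries. Members below 1 FPKM elsewhere, Krt14 among them, passed the FPKM minimum only through this treated library. Their higher values therefore followed in part from the filter. The 8 genes with the highest ratios (Krt14, Krt1, Krt10, Krtdap, Dmkn, Krt5, Calm4 and Sbsn) were genes of keratinocytes. Krt14 (chromosome 11, 100203162 to 100207510) was at 18.5 against 0.293 FPKM, Krt10 at 31.2 against 1.44 FPKM and Acta1, skeletal muscle actin (chromosome 8, 123891767 to 123894736), at 143 against 55.3 FPKM. The adipocyte list, with 4 members, had a median of 0.49, and did not lie apart with no FPKM minimum or a minimum of 5. Over 11716 genes, 174 were higher and 41 lower by size. Without the genes of the epidermis, muscle and adipocyte lists the counts were 149 and 41. Dmkn and Calm4 are in none of these lists, so keratinocyte genes remained among those counted. The counts moved with the processing, to 361 and 72 with a pseudocount of 0.1, to 69 and 12 with a pseudocount of 5 and to 370 higher after rescaling to TPM. Of the 46 lists, 26 lay apart with a higher and 5 with a lower median.

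The next comparison asked how tumours with overexpressed IL-34 responded to anti-PD-1. In this line MHC class II genes were at lower levels in the treated library than in the untreated library, while type I interferon genes were higher. Cd8a was at 3.42 against 5.77 FPKM, Cd3e at 6.25 against 9.69 FPKM and Ifng at 3.16 against 2.70 FPKM. Cd74 was at 852 against 1378 FPKM, 1.62-fold lower. Cxcl9, an interferon-γ-induced chemokine for T cells, was at 87.5 against 106 FPKM, and Cxcl10, a related chemokine, at 107 against 81.4 FPKM.

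Of the lists that lay apart, pan-T cell genes had a median of −0.18, with 3 of 14 above 0, CD4 and CD8 genes −0.35, inhibitory receptors −0.28, cytotoxic effectors −0.20, MHC class II −0.66 and pan-macrophage genes −0.16. No member of the pan-T cell, MHC class II or pan-macrophage lists was past the size rule. The PD-1 axis median of −0.34 and the complement median of −0.14 did not lie apart with the mean (−0.15 and −0.09). Type I interferon genes had a median of 0.38, with Oas2, an antiviral enzyme, at 19.6 against 11.8 FPKM and Isg15 at 77.3 against 51.5 FPKM. Interferon-γ response genes had a median of 0.14, T cell attracting chemokines 0.28, inflammatory monocyte genes 0.28, alternatively activated macrophage genes 0.24, fibroblast and matrix genes 0.25 and glycolysis and hypoxia genes 0.12. Collagen Col1a1 was at 104 against 62.2 FPKM in this line and at 127 against 59.6 FPKM in the deficient line. Endothelial genes had a median of −0.23. The natural killer, regulatory T cell, naive and memory T cell and MHC class I lists, with medians of 0.00, −0.08, 0.02 and −0.03, did not lie apart.

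Skeletal muscle genes were lower in this treated library, with a median of −1.32 and 9 of 15 members lower by size. Acta1 was at 3.27 against 39.0 FPKM and Ckm, muscle creatine kinase, at 1.56 against 10.7 FPKM. The adipocyte list had a median of −0.94 and the epidermis list one of 0.00. Among the highest genes were Serpinb2 at 6.21 against 1.87 FPKM, Pf4 at 34.8 against 16.8 FPKM, the monocyte chemokine Ccl7 at 92.9 against 47.7 FPKM and Hmox1, a heme-degrading enzyme, at 106 against 58.8 FPKM. Ccl7 and Hmox1, with log2 ratios of 0.95 and 0.84, did not reach the size rule. Over 11461 genes, 6 were higher and 32 lower by size, and without the epidermis, muscle and adipocyte lists 21 were lower. The counts were 32 and 56 with a pseudocount of 0.1 and 1 and 13 with a pseudocount of 5.

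**Figure D1:**
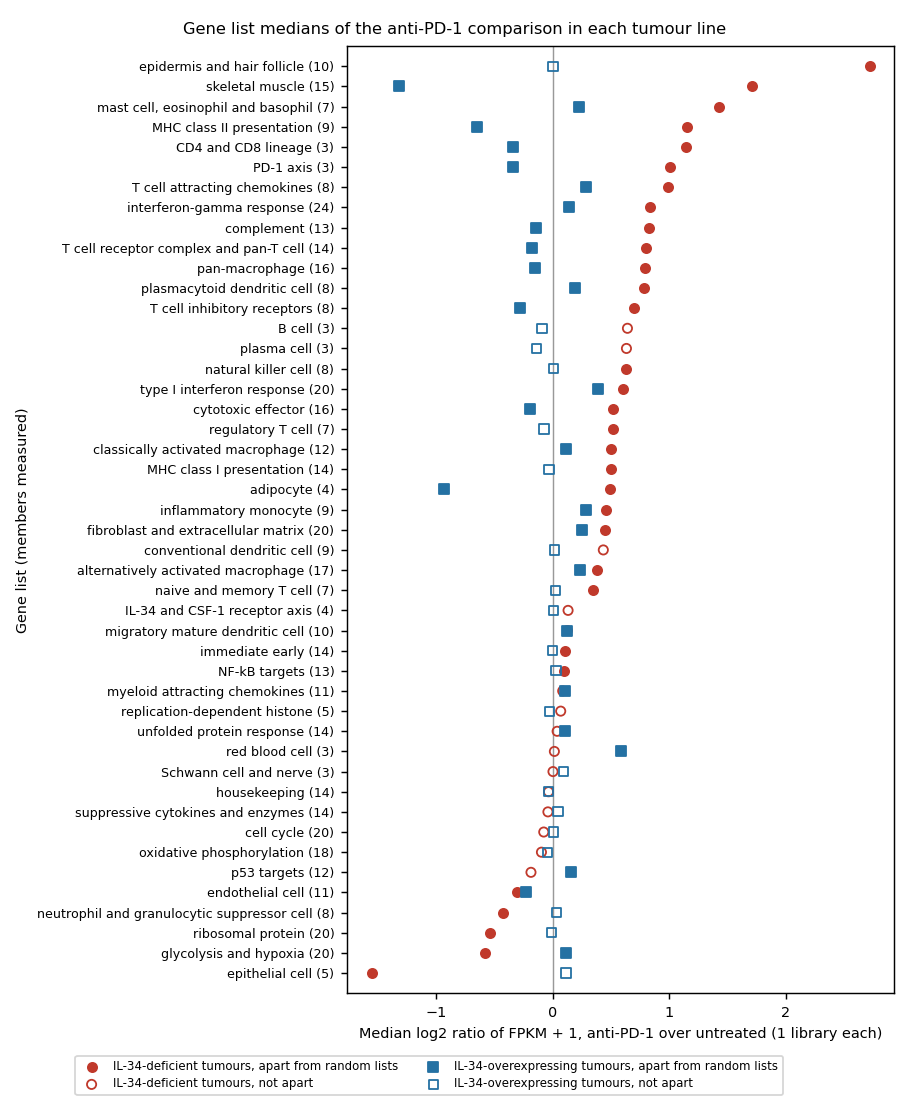
Median log2 ratio of FPKM + 1, anti-PD-1 over untreated, for each of the 46 gene lists in IL-34-deficient tumours (red circles) and IL-34-overexpressing tumours (blue squares), with 1 library per group. Filled symbols are medians that lay apart from 10000 random lists; MHC class II presentation was at 1.15 in the deficient line and −0.66 in the overexpressing line, and skeletal muscle at 1.71 and −1.32.

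The difference of the anti-PD-1 responses, overexpressing minus deficient, asked whether the response differed between the lines. The MHC class II, pan-T cell, CD4 and CD8, pan-macrophage and complement lists had the lower value in the overexpressing line. The medians were −1.67 for MHC class II, with 8 of 9 members past the size, −1.02 for pan-T cell genes, with 7 of 14, −1.59 for CD4 and CD8 genes, −0.93 for pan-macrophage genes, with 7 of 16, and −1.06 for complement, with 8 of 13. The alternatively activated macrophage, inflammatory monocyte and naive and memory T cell lists, with medians of −0.09, −0.10 and −0.17, did not lie apart. The interferon-γ list had a median of −0.60 and the type I interferon list one of −0.22. Ccl5 differed by a log2 of −2.45, Ccl8, a monocyte chemokine, by −2.58 and Cd8a by −1.76. Skeletal muscle and epidermis genes had medians of −3.18 and −2.54, and Acta1 differed by −4.58. The epidermis median followed in part from the filter, as members such as Krt14 passed the FPKM minimum only through the treated deficient library. On the higher side, epithelial genes had a median of 1.67, with 3 of 5 past the size. Those 3 are keratins that passed the FPKM minimum only through the untreated deficient library. Glycolysis and hypoxia genes had a median of 0.66, with 6 of 20 past the size. Car9 differed by 2.47, Serpinb2 by 2.75 and Hmox1 by 2.06. Over 11814 genes, 62 had a higher and 257 a lower difference by size. Without the genes of the epidermis, muscle and adipocyte lists the counts were 62 and 231, with a pseudocount of 0.1 they were 128 and 462, with a pseudocount of 5 they were 20 and 90, and after rescaling to TPM 457 were lower. With 1 library per group the difference had no residual degrees of freedom and was not tested. Genes past the size rule in both lines numbered 0 higher in both and 3 lower in both (Gzmd, Gzmf and Gzmg). Another 15 were higher in the deficient and lower in the overexpressing line, and 1 (Serpinb2) was the reverse. The 15 included the skeletal muscle genes Acta1, Ckm and Tnnc2 and the uncertain Oaz1-ps. They held no member of the pan-T cell, MHC class II or pan-macrophage lists, as none passed the size rule in the overexpressing line. The ratios of the lines correlated across genes at r of −0.07.

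The comparison of the lines without treatment asked how they differed in the absence of anti-PD-1. No library came from a line with unaltered IL-34. Loss of IL-34, its overexpression and other differences between the lines therefore cannot be told apart. Besides Il34, granzymes C to G were higher in the overexpressing tumour. Gzmd was at 136 against 46.0 FPKM, Gzmf at 148 against 53.8 FPKM and Gzmg at 154 against 53.2 FPKM. Lcn2, an iron-scavenging protein, was at 4.01 against 9.89 FPKM, a log2 ratio of −1.12. Saa3, an acute-phase protein, at 7.74 against 15.5 FPKM, and Cxcl13, a chemokine for B cells, at 3.17 against 6.70 FPKM, did not reach the size rule, with log2 ratios of −0.92 and −0.89.

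Immune gene lists were also compared between the untreated lines. Pan-T cell genes had a median of −0.26 and CD4 and CD8 genes one of −0.44, with 0 members of either past the size, and Cd8a was at 5.77 against 8.61 FPKM. The interferon-γ list had a median of −0.11, the type I interferon list −0.21, MHC class I −0.14, neutrophil genes −0.26, glycolysis and hypoxia genes −0.21 and myeloid attracting chemokines −0.24. MHC class II genes had a median of −0.12, which did not lie apart with a pseudocount of 0.1 or 5. Natural killer genes had a median of 0.17, endothelial genes one of 0.24 and cytotoxic effectors one of 0.08, with 4 granzymes higher by size. Pan-macrophage genes had a median of 0.00 and alternatively activated macrophage genes one of 0.05, and both means were below 0 (−0.01 and −0.02). Mrc1 was at 45.4 against 43.2 FPKM and Arg1 at 104 against 131 FPKM. Skeletal muscle genes had a median of −0.24, epidermis genes one of −0.37 and epithelial genes the lowest, −1.56 over 5 members. The epithelial value rests on keratins that passed the FPKM minimum only through the untreated deficient library. Over 11467 genes, 14 were higher and 11 lower by size. These were 8 and 1 with a minimum of 5 FPKM, 24 and 26 with a pseudocount of 0.1, and 8 and 0 with a pseudocount of 5. The Rps27 model, at 53.6 against 10.4 FPKM, overlaps another model and is uncertain.

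The comparison of the lines under anti-PD-1 asked how treated tumours differed with IL-34. The overexpressing tumour had lower levels of T cell, MHC class II, interferon-γ and complement genes. Cd8a was at 3.42 against 20.2 FPKM, 5.91-fold lower, Cd3e at 6.25 against 28.5 FPKM and Ccl5 at 34.1 against 223 FPKM, 6.54-fold lower. H2-Ab1 was at 183 against 976 FPKM, 5.33-fold lower. Gzmb, in contrast, was at 99.1 against 96.2 FPKM and Gzma at 64.2 against 50.8 FPKM.

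Pan-T cell genes had a median of −1.25, with 10 of 14 lower by size, CD4 and CD8 genes −2.04 with all 3 lower, inhibitory receptors −1.14 with 5 of 8 lower, and the PD-1 axis −1.59. MHC class II genes had a median of −1.87, with 8 of 9 lower, MHC class I genes −0.67, interferon-γ genes −0.75, T cell attracting chemokines −1.25, pan-macrophage genes −0.95 and complement −1.01. Type I interferon genes had a median of −0.43 and mast cell, eosinophil and basophil genes one of −0.95. Cytotoxic effectors had a median of −0.99, with 8 lower and 4 higher by size, natural killer genes −0.53 and alternatively activated macrophage genes −0.20, and none of these 3 lay apart with the mean (−0.12, −0.47 and −0.11). Lyve1, a receptor of lymphatic vessels and some macrophages, was at 15.1 against 2.12 FPKM and Gzmd at 64.3 against 6.83 FPKM. Glycolysis and hypoxia genes had a median of 0.45, endothelial genes one of 0.37 and ribosomal protein genes one of 0.43. Skeletal muscle genes had a median of −3.67 and epidermis genes one of −3.08, the latter in part through the same filter on the treated deficient library. Over 11736 genes, 46 were higher and 278 lower by size, and without the epidermis, muscle and adipocyte lists 46 were higher and 252 lower. The counts were 80 and 476 with a pseudocount of 0.1 and 18 and 108 with a pseudocount of 5, and 431 were lower after rescaling to TPM.

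**Figure D2:**
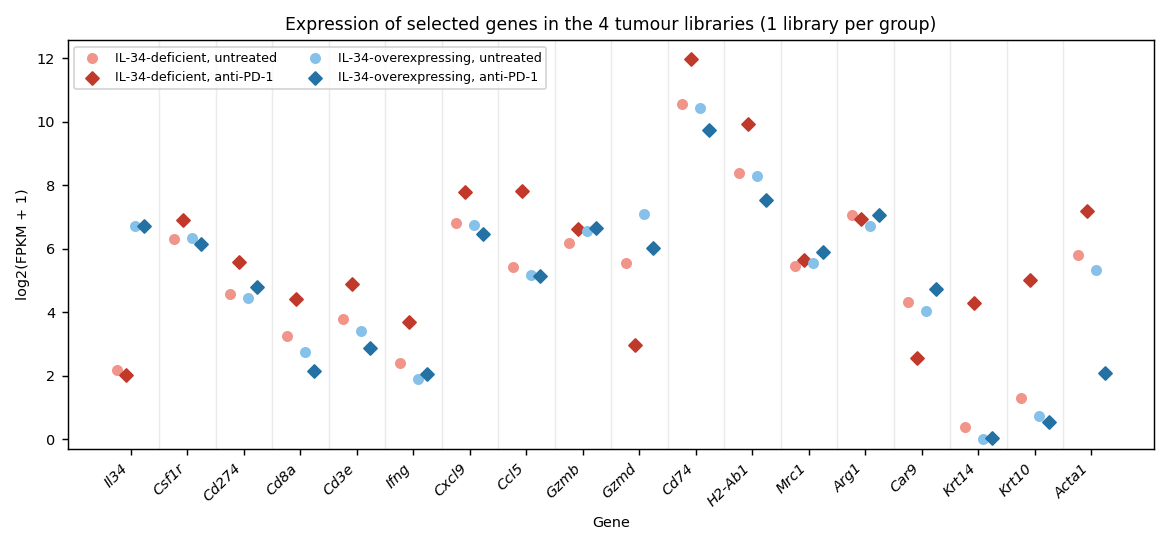
FPKM of 18 genes in the 4 tumour libraries, on a log2(FPKM + 1) axis, with 1 point per library. Il34 was at 104 FPKM in both overexpressing libraries, and Cd8a, Cd74 and Krt14 had their highest points, 20.2, 3978 and 18.5 FPKM, in the anti-PD-1 IL-34-deficient library.

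The additive limma fit asked which genes differed with IL-34 over both treatments. Il34 was the only gene called, with a log2 difference of 4.62 (SE 0.10) and a limma adjusted p of 7.45e-06, higher in both overexpressing libraries. Of 11814 genes, 653 had an unadjusted limma p below 0.05. Their share cannot show whether there was an effect, because a gene that moved in 1 library only adds as much to the error as to the effect. Saa3 followed with a log2 difference of −1.06 (SE 0.11, limma adjusted p of 0.174), and Gzmf with 1.97 (SE 0.22, limma adjusted p of 0.184). Gzmd, Gzme and Gzmg each had a limma adjusted p of 0.207. By the size rule 7 genes were higher in both treatments (Il34, Gzmc, Gzmd, Gzme, Gzmf, Gzmg and BC002163) and 1 was lower in both (Fam25c), and 1 was lower without and higher with anti-PD-1 (Gm4070); the last 2 were named after their values were seen, because each makes up a count. With 3 libraries no second factor could be fitted, so fits that left out a library compared an arm of both treatments with an arm of a single treatment. Without the untreated deficient library 127 genes were higher and 411 lower, without the untreated overexpressing library 1 was higher and 2 lower, and without the treated overexpressing library 2 were higher, whereas all 4 libraries with no second factor gave 1 higher and 0 lower. With no FPKM minimum, limma called 0 genes, with 509 at an unadjusted p below 0.05, and with a minimum of 5 it called Saa3 lower as well.

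For anti-PD-1 over both lines, limma called 0 genes higher and 0 lower, with a smallest limma adjusted p of 0.398. Of 11814 genes, 530 had an unadjusted limma p below 0.05, a share that again cannot show whether there was an effect. Gzmf had a log2 difference of −1.90 (SE 0.22), Gzmg one of −1.98 (SE 0.28) and Saa3 one of 0.81 (SE 0.11), each with a limma adjusted p of 0.398. Other genes with the same direction in both lines were Clec10a, a macrophage lectin, at 8.51 against 3.46 and 5.72 against 3.0 FPKM, and the chemokine Ccl22, at 6.07 against 3.38 and 4.62 against 2.11 FPKM. Without the treated overexpressing library, limma called 1245 genes higher and 1161 lower, and without the treated deficient library 12 higher and 43 lower, again with no second factor, so that treatment and line were partly mixed. All 4 libraries with no second factor gave 0 calls, with 391 genes at an unadjusted p below 0.05.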

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

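All tests of explanations in this part were chosen after the results had been seen. For 11 of the gene lists the medians lay apart in opposite directions with anti-PD-1 in the IL-34-deficient and IL-34-overexpressing lines; with 1 library per group, the difference between the lines was not tested. The median difference of the log2 ratios, overexpressing minus deficient, was −1.06 for the PD-1 axis, −1.02 for pan-T cell genes, −1.59 for CD4 and CD8 genes, −0.91 for cytotoxic effectors and −0.99 for inhibitory receptors. It was −0.93 for pan-macrophage genes, −1.67 for MHC class II presentation and −1.06 for complement. It was 0.66 for glycolysis and hypoxia genes, −3.18 for skeletal muscle genes and −1.22 for adipocyte genes. The adipocyte difference itself did not lie apart under every setting. Under other settings some of these medians no longer lay apart in 1 line: cytotoxic effectors (mean) and adipocyte genes (no minimum, or a minimum of 5) in the deficient line, and the PD-1 axis and complement (mean) in the overexpressing line.

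The higher immune gene levels in the anti-PD-1 IL-34-deficient library coincided with higher epidermis and muscle genes. A lower share of tumour cells alone would raise other cell types alike. The lowest quartile of pan-T cell members (0.66) lay 0.87 above the highest quartile of endothelial members (−0.21), and the highest quartile of neutrophil members was 0.23. Median FPKM was higher for pan-macrophage genes (115 against 71.3) and for fibroblast and matrix genes (17.9 against 12.9). The cell types thus did not move alike. Endothelial genes were also lower with anti-PD-1 in the overexpressing line, so their fall may be separate. A lower share of tumour cells therefore stays open for the immune genes. In the order untreated and treated deficient, then untreated and treated overexpressing, median FPKM was 7.29, 22.3, 5.71 and 0.574 for muscle genes, 3.25, 6.48, 2.68 and 2.45 for pan-T cell genes, and 0.339, 9.99, 0 and 0.0179 for epidermis genes. The untreated library of this line differed as well: epithelial genes had a median of −1.56 with anti-PD-1 in this line and −1.56 between the untreated lines. Both values rest on a few keratins with low FPKM that passed the minimum only through that untreated library. Tissue next to the tumour and the part of the tumour sampled stay open, since each group has 1 library. So do a response to anti-PD-1 that depends on IL-34, another difference between the lines and a difference between single tumours.

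Granzymes C to G were lower with anti-PD-1 in the IL-34-deficient line, with sums of 39.6 against 220 FPKM. Reads moved between near-identical granzyme genes would leave their total in place, but the sum of all 10 granzyme genes had a log2 ratio of −0.82. Fewer T and natural killer cells as a whole would lower both of those lists, whereas the lower of the medians was 0.63. The lists do not separate cytotoxic cells inside the tumour from other T and natural killer cells, so fewer cytotoxic cells stays open. The C to G sum was also 1.98-fold lower with anti-PD-1 in the overexpressing line, and 2.71-fold and 7.61-fold higher in the overexpressing than in the deficient line without and with treatment. A different state of the cytotoxic cells may account for this, as a hypothesis that was not tested. Differences between single tumours and other differences between the lines stay open.

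Gvin1, an interferon-induced GTPase gene, and the overlapping model Gm4070 were singled out after their values were seen. Over both of their loci Gvin1 was at 3.70 against 18.7 FPKM with anti-PD-1 in the overexpressing line, and Gm4070 at 20.8 against 3.66 FPKM. The sum of the models was 24.5 against 22.3 FPKM, a log2 ratio of 0.13, so the opposite movements could come from fragments assigned to one model or the other. No biological explanation was tested.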

How the results depend on the processing

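The added counts without the epidermis, muscle and adipocyte lists were chosen after the data had been seen, and all other alternatives before. Only lists that lay apart in the main setting were followed under other settings, so lists that came to lie apart elsewhere were not counted. Of the 1133 medians so recomputed, 1085 kept their direction and lay apart, 45 no longer lay apart and 3 reversed. Median-ratio scaling, with 143 of these, shifts members and random lists nearly alike and could hardly change the outcome. Of 480 values of ranked genes, 468 kept their side of the size rule, 9 dropped below it and 3 passed it. The reversals were plasmacytoid dendritic cell genes with anti-PD-1 in the overexpressing line (−0.0617 with a minimum of 5) and, between the untreated lines, the means of pan-macrophage (−0.00691) and alternatively activated macrophage genes (−0.0240); the cause was not tested. With the mean, 17 lists lay apart lower between the treated lines, against 27 with the median.

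Counts of genes by size moved with the pseudocount, which sets how far genes with low values can move. With 0.1, the counts higher and lower were 361 and 72 for anti-PD-1 in the deficient line, 32 and 56 in the overexpressing line, 24 and 26 between untreated lines, 80 and 476 between treated lines and 128 and 462 for the difference of responses. With 5 they were 69 and 12, 1 and 13, 8 and 0, 18 and 108, and 20 and 90, in the same order. With a size of 1.5, a stricter rule, they were 54 and 14, 1 and 15, 6 and 5, 20 and 119, and 28 and 99. With a minimum of 5, fewer genes were counted: 23 lower in the deficient line, 15 lower in the overexpressing line, 8 higher and 1 lower between untreated lines, 174 lower between treated lines and 160 lower for the difference. The share of higher genes with anti-PD-1 in the overexpressing line was 15.8%. It was 36.4% with a pseudocount of 0.1 and 25% with a minimum of 5, and 7.14% with a pseudocount of 5 and 6.25% with a size of 1.5. Between untreated lines the share was 56.0%, against 88.9% with a minimum of 5 and 48.0% and 100% with pseudocounts of 0.1 and 5. Rescaling to TPM moved the median of all genes by 0.14 for anti-PD-1 in the deficient line and by −0.13 for the difference of responses, and gave 370 higher in the deficient line, 11 higher in the overexpressing line, 431 lower between treated lines and 457 lower for the difference. Without the epidermis, muscle and adipocyte lists, 21 genes were lower in the overexpressing line.

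For limma, no FPKM minimum gave 0 genes higher with IL-34 and a minimum of 5 gave 1 lower, Saa3. Leaving out each library in turn gave 1 to 127 higher and 0 to 411 lower for IL-34, and 0 to 1245 higher and 0 to 1161 lower for anti-PD-1. These fits had no second factor, so line and treatment were partly mixed in them, and the lone library of an arm was assumed to vary like the others. No paired analysis was possible because the labels carry no replicate numbers and pair no tumours across groups. The additive fit blocked on the other factor only. Total depth is unknown, so no limit from fragment counts could be set on low values.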

Other observations

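Effector genes were set beside the pan-T cell median, whose members had log2 ratios from 0.51 to 1.30 with anti-PD-1 in the IL-34-deficient line. Relative to that median of 0.80, Ccl5 was at 1.60, Lag3 at 0.60, Nkg7 at 0.50, Ifng at 0.48, Prf1 at −0.22, Gzmb at −0.36 and Gzma at −0.50. The ratios of Nkg7, Ifng and Prf1 (1.30, 1.28 and 0.58) lay within the range of the pan-T cell members. Those of Ccl5 (2.40) and Lag3 (1.40) lay above it and those of Gzma and Gzmb (0.30 and 0.44) below it. The pseudocount shrinks ratios at low FPKM, and the pan-T cell list had median FPKM of 3.25 untreated and 6.48 treated. These positions therefore depend in part on expression level. In the overexpressing line, Gzmb was at 0.27 relative to the pan-T cell median, Gzma at 0.17, Ccl5 at 0.13, Ifng at 0.35, Nkg7 at −0.05 and Prf1 at −0.10. Between the treated lines, overexpressing against deficient, Gzma, Gzmb and Prf1 stood above the median by 1.58, 1.29 and 1.02, while Nkg7, Ifng and Ccl5 were at −0.51, −0.38 and −1.43. Between the untreated lines Gzma, Gzmb and Prf1 stood above it by 0.90, 0.65 and 0.90, and Nkg7, Ifng and Ccl5 were at 0.04, −0.25 and 0.04. These values were looked at after the data had been seen and were not tested.

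Keratins of simple epithelia were measured in the untreated IL-34-deficient library and near 0 elsewhere. Krt8 was at 1.94 FPKM there and at 0 to 0.0809 FPKM in the other libraries, Krt18 at 2.29 against at most 0.108 FPKM and Krt19 at 2.74 against at most 0.331 FPKM. The epithelial list, with 5 members, had a median log2 ratio of −1.56 with anti-PD-1 in the deficient line and −1.56 between the untreated lines. As these keratins passed the FPKM minimum only through the untreated deficient library, their lower values elsewhere followed in part from the filter. Red blood cell genes, with 3 members, had a median of 0.58 with anti-PD-1 in the overexpressing line and 0.76 between the treated lines. p53 target genes had medians of 0.16 and 0.29 in those comparisons. Cell cycle, oxidative phosphorylation and housekeeping genes lay apart in none of the 5 comparisons, with cell cycle medians from −0.08 to 0.11.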
